A study of Mus musculus with 6 samples.

How the data were processed

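Total RNA from mouse sciatic nerve, the main nerve of the hind limb, was extracted with Trizol and RNeasy columns and made into sequencing libraries with the Illumina TruSeq RNA kit, per the labels' protocols. The series' design text gives 3 cKO mice and 3 wild-type mice as controls. The labels of the cKO samples name YAP and TAZ together and do not spell out cKO, so the groups are called here as they are labelled. The replicates are separate mice per the design text, though each library holds transcripts of both sexes. The age of the animals, the driver of the deletion, the deleted part of each gene, the strand setting of the kit and any pooling of nerves are not given in the sources used here.

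The deposited files hold raw read counts per gene symbol, 1 file per sample, with no normalization by the authors. The submitters' processing notes name the aligner TopHat2 version 2.0.13, the counting program HTSeq with no version, and the genome build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here. Each file lists 24421 genes and the closing lines that HTSeq adds. Those closing lines were kept out of library sizes and tests. Reads given to no gene made up 12.07% to 14.26% of all counts in a file, and reads shared between genes 1.635% to 2.818%. The other closing lines were at 0. Because whole genes were counted, reads from a deleted exon cannot be told from reads of the rest of a gene. Overlapping and antisense genes cannot be told apart without a stated strand setting.

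Gene positions were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, by gene symbol. A position was found for 23376 of the 24421 symbols (95.7%). GC content and transcript length came from the same annotation and were found for 14256 of the 14789 tested genes (96.4%).

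The total of gene counts per library ranged from 24651262 to 47044158. A gene with 0 counts could still have a level of up to 0.122 CPM (counts scaled to library size) in the shallowest library and 0.0638 CPM in the deepest, taking 3 counts as the limit. Such limits cover counting error only. Libraries of a group differed from each other by far more than counting noise, with a chi-square per degree of freedom of at least 12.9 over genes, so no library was treated as a second copy of another.

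The groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 14789 genes, and library sizes were scaled by TMM factors. The quasi-likelihood F test was fitted on all 6 libraries with the group as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are cKO-labelled over wild-type libraries, and the standard error (SE) is the log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors and given as mean ± SD over 3 libraries per group.

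Before the data were examined, 32 gene lists were fixed, together with the test, the alternatives and the rule for genes named in the text. The lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Their p-values are two-sided and adjusted over the 32 lists. The lists hold 535 tested genes, of which 11 stand in more than 1 list. Camera with an estimated correlation, camera on ranks and fry were alternatives. Counts of called members come from the edgeR test of all genes, and each is set beside the count adjusted over the list alone.

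Genes were named by 3 rules. Yap1 and Wwtr1 were always named. Among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, the 12 with the largest and the 12 with the smallest log2 fold change were taken. From each list, up to 4 members (lists of the study's theme) or 2 members (lists of other cell types and RNA quality) were taken in order of p, and every laminin receptor could be named. Predicted genes and near-identical gene copies among the 24 are given as a count. The rules gave 120 genes. All other genes named in the text, such as Mbp, Pmp22, Dhh, Ctgf, Cyr61, Ankrd1, Sox10, Mki67, Ccnd1 and the members of lists chosen later, were chosen after their values were seen. Some genes that the rules or the lists gave are not reported here.

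The pipeline was tested on simulated counts for this comparison, drawn from the real means and library sizes with a seeded set of changed genes. Of 14644 simulated genes tested, those changed by a log2 size of 0.5 were called in 15 of 66 cases (22.73%), of 1 in 51 of 67 cases (76.12%) and of 2 in 61 of 67 cases (91.04%). Of 14444 unchanged genes, 13 were called. In a second simulation with 14641 genes tested, camera found the 1 changed list with both kinds of correlation and called 0 of 40 unchanged lists. The simulated genes varied independently, unlike genes in tissue.

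Alternatives fixed before the data were examined were DESeq2's size factors in edgeR, upper-quartile factors, total counts only, no filter, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block and leaving out each library in turn. Added after seeing the data were counts thinned to the total of the shallowest library and the skeletal muscle level as a covariate. The removal of each library's trend with GC content and transcript length was also added then. The muscle level is the mean log2 CPM of the genes of the muscle list. The edgeR p-values set the difference between the groups against the spread between the libraries within them.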

Results

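RNA was measured in 3 libraries of sciatic nerve labelled cKO for YAP and TAZ and in 3 libraries labelled wild-type (WT). YAP and TAZ are transcriptional co-activators at the end of the Hippo pathway, encoded by Yap1 and Wwtr1, and they act through TEAD transcription factors. The comparison asks how the nerve's transcripts differ between the genotypes, with the series' title pointing to myelination, Schwann cell proliferation and laminin receptors. Gene counts came to 32003497, 24651262 and 30193878 in the libraries cKO 1, 2 and 3 and to 47044158, 41270894 and 43075676 in WT 1, 2 and 3. Every WT library was therefore deeper than every cKO-labelled one (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Correlations of log2 CPM lay between 0.9788 and 0.9886 within groups and between 0.9561 and 0.972 across them, and the first principal component, with 55.6% of the variance, separated the groups. Each of the 6 libraries held reads of both Xist, which female cells express (133.9 to 258.0 CPM), and the Y-linked Ddx3y (8.93 to 47.96 CPM), transcripts of both sexes that a single mouse does not normally give together, and the labels do not say whether nerves were pooled.

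Neither targeted gene was called lower. Yap1 (mm10 chromosome 9, 7931999 to 8004596, minus strand) stood at 108.1, 108.8 and 102.6 CPM in cKO 1, 2 and 3 and at 120.4, 123.7 and 121.7 CPM in WT 1, 2 and 3, a log2 fold change of -0.20 ± 0.08 (SE, n = 3 per group) with an edgeR adjusted p of 0.145. Wwtr1 (chromosome 3, 57455649 to 57575910, minus strand) rose, from 253.8 to 284.2 CPM in the WT libraries to 337.4 to 372.0 CPM in the cKO-labelled ones. Its log2 fold change was 0.40 ± 0.09 (edgeR adjusted p = 0.0208), and the call was lost when cKO 3, WT 1 or WT 2 was left out (edgeR adjusted p = 0.117, 0.0914 and 0.0518). A deletion of part of a gene in some of a nerve's cells need not lower the count over the whole gene, and the deleted parts are not given in the sources used here. These counts therefore check neither label, and every direction given here is drawn from the labels alone.

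Of 14789 genes tested, 1618 changed: 706 were higher and 912 lower in the cKO-labelled libraries (edgeR, adjusted p under 0.05). The change was at least 2-fold for 394 of the higher and 261 of the lower genes. The groups did not overlap for 31.1% of genes, against 10% by chance for 3 against 3. Lower genes made up 56.4% of the calls with TMM scaling but 32.3% with total counts only, which shifts the median log2 fold change of all genes by 0.125. Left-out libraries that moved the counts by over 1.5 times were cKO 3 (735 changed, 276 higher, 459 lower), WT 2 (984, 409 and 575), cKO 2 (1072 changed, 395 higher), WT 1 (449 higher) and WT 3 (1075 higher). Skeletal muscle transcripts also separated the groups, and with their level as a covariate 38 genes were called, 5 higher and 33 lower. The median SE of the 1618 genes grew from 0.141 to 0.287 in that fit, while 1528 of them kept their sign.

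Genes of the myelin sheath fell. Of 24 tested proteins of peripheral myelin and the paranode, 21 were lower and 0 higher in the cKO-labelled libraries (21 adjusted over the list alone), with a median log2 fold change of -1.56. Mbp, which compacts the cytoplasmic face of myelin, fell 4.06-fold (log2 -2.02 ± 0.21, SE, n = 3 per group), and Pmp22 fell 3.83-fold (log2 -1.94 ± 0.20). Gjb1, the gap junction protein connexin 32, fell 4.53-fold from 81.3 ± 14.3 to 17.98 ± 3.00 CPM, and Pmp2, a fatty acid binding protein of myelin, fell 5.22-fold. Mag and Mal fell 3.06-fold and 3.01-fold. Among the members that did not pass were Dhh (log2 0.03 ± 0.09) and Arhgef10. Camera gave the list an adjusted p of 2.44e-19 with the preset correlation and an adjusted p of 0.58 with an estimated correlation. Of the other alternatives, fry gave an adjusted p of 0.00958 and rank-based camera an adjusted p of 7.63e-11. In the fits that left out 1 library, 18 to 21 members were called lower.

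The genes of cholesterol synthesis fell together. All 25 tested members of that list were lower (25 adjusted over the list alone; edgeR), from -0.58 for Srebf2 to -2.27 for Tm7sf2 on the log2 scale, with a median of -1.52. Mvd, the last enzyme before isoprenoid units, went from 149.8 ± 13.5 to 47.3 ± 3.24 CPM, Acat2 from 197.4 ± 19.1 to 58.5 ± 6.26 CPM and Fdps from 528.1 ± 69.0 to 153.7 ± 22.1 CPM. In the list of fatty acid synthesis, 12 of 17 members were lower and 1 higher (13 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.84. Acss2, which makes acetyl-CoA from acetate, fell 3.70-fold, Fads1 fell 2.12-fold, Acly 1.96-fold and Elovl1 1.70-fold. The higher member was Thrsp, a lipogenic gene of fat and liver (log2 1.72 ± 0.45), whose call held only without WT 3 among the fits that left out 1 library. Camera adjusted p-values were 1.45e-25 for cholesterol and 1.41e-07 for fatty acid synthesis with the preset correlation. With an estimated correlation the camera adjusted p-values were 0.58 and 0.626. Fry gave adjusted p-values of 0.00958 and 0.0222, and rank-based camera 8.63e-13 and 0.000287. In the fits that left out 1 library, 22 to 25 cholesterol genes and 11 to 13 fatty acid genes were called lower. With the muscle level as a covariate, 2 of 24 myelin, 9 of 25 cholesterol and 1 of 17 fatty acid genes were still called lower, while the list medians went to -1.77, -1.76 and -1.11.

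**Figure D1:**
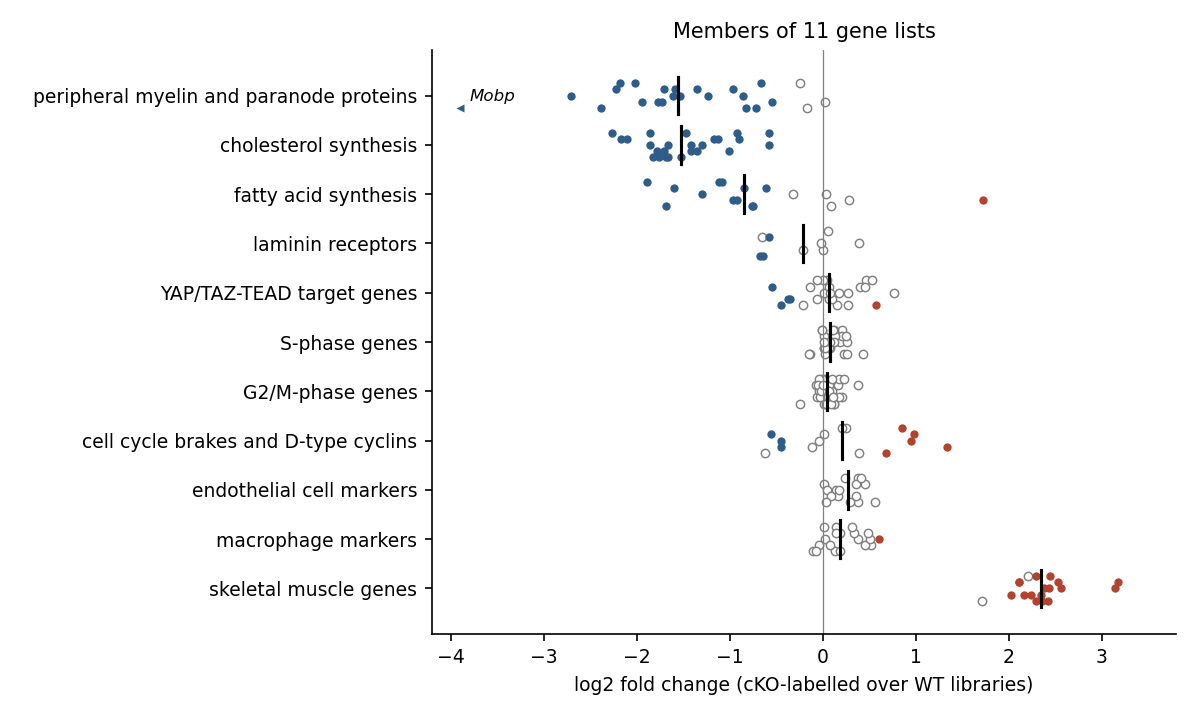
Log2 fold changes, cKO-labelled over WT libraries, of the tested members of 11 gene lists (1 point per gene; filled points passed an edgeR adjusted p of 0.05, blue for lower and red for higher; black bars are list medians). Myelin (median -1.56) and cholesterol genes (median -1.52) lie to the left, skeletal muscle genes (median 2.35) to the right, and the S-phase and G2/M-phase genes around 0 with none called; Mobp, with almost no reads in the cKO-labelled libraries, is drawn as a triangle at the edge because its fitted fold has no reliable size.

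Of 9 tested laminin receptors, 3 fell and 0 rose (edgeR). Itga6 (chromosome 2, 71745616 to 71858416), which forms laminin-binding integrins with Itgb1 or Itgb4, went from 1261 ± 89.0 to 793.0 ± 73.0 CPM, a log2 fold change of -0.67 ± 0.11 (edgeR adjusted p = 0.00529). Bcam (chromosome 7, 19756131 to 19771016), a receptor for laminin alpha 5 chains, went from 97.0 ± 13.6 to 62.2 ± 5.60 CPM (log2 -0.64 ± 0.12, edgeR adjusted p = 0.00993). Itgb4 (chromosome 11, 115974709 to 116008412) went from 92.8 ± 8.42 to 62.4 ± 13.4 CPM (log2 -0.57 ± 0.15, edgeR adjusted p = 0.0437). Dag1, which encodes dystroglycan, did not differ beyond the spread, at 1020 ± 63.3 CPM in WT and 1022 ± 166 CPM in the cKO-labelled libraries. The others that did not pass were Itgb1 (log2 -0.02 ± 0.09, above 0 with upper-quartile factors, total counts, the GC and length correction and without cKO 1), Itga1 (0.39 ± 0.12, called higher with upper-quartile factors, total counts, DESeq2 and the GC and length correction), Itga2 (-0.65 ± 0.31), Itga3 (0.06 ± 0.37) and Itga7 (-0.21 ± 0.11). Adjusted over the list alone, 3 were lower and 1 higher. The list as a whole was not called (camera adjusted p = 0.102, and adjusted p = 0.689 with an estimated correlation), but it was called lower with the muscle level as a covariate (camera adjusted p = 0.00615, and adjusted p = 0.754 with an estimated correlation), its median log2 fold change going from -0.21 to -0.60 with 0 members called. Itga6 was called in all 6 fits that left out 1 library and Bcam in 5, all but the one without cKO 3. Itgb4 was called only without cKO 2, and its call was lost with total counts (edgeR adjusted p = 0.0885).

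**Figure D2:**
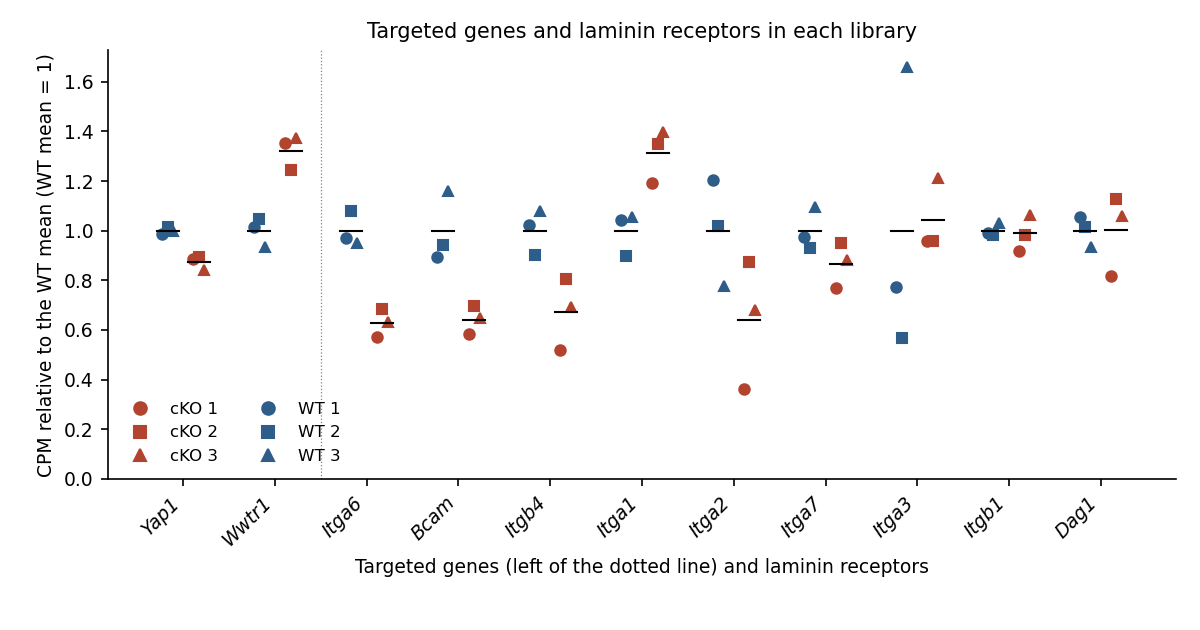
CPM of Yap1, Wwtr1 and 9 laminin receptors in each of the 6 libraries, divided by the mean of the 3 WT libraries (symbols give the replicate, blue WT and red cKO-labelled, black bars the group means). Yap1, Itga6, Bcam and Itgb4 lie lower in every cKO-labelled library than in any WT library, and Wwtr1 and Itga1 lie higher. Of these, Yap1 and Itga1 did not pass the edgeR test.

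Partners of dystroglycan moved both ways. Of 16 tested, 6 fell and 3 rose (6 and 4 adjusted over the list alone). Drp2 (chromosome X, 134404551 to 134456573), which links dystroglycan to periaxin in myelinating Schwann cells, fell 6.50-fold (log2 -2.70 ± 0.31, edgeR adjusted p = 0.00123). Prx, which encodes periaxin, fell 2.35-fold, Utrn 2.06-fold and Sgcd 1.98-fold, and Sgcb and Dmd also fell. Dtna rose, as did Sgca, a sarcoglycan of striated muscle. The list was called lower only with the muscle level as a covariate (camera adjusted p = 0.0018, and adjusted p = 0.654 with an estimated correlation; without it camera adjusted p = 0.121, and adjusted p = 0.689 with an estimated correlation), and its higher calls went from 3 to 0 without cKO 3 and to 1 without cKO 2. Among 21 laminins and other basal lamina genes, 4 fell and 1 rose (5 and 2 adjusted over the list alone). Lama2, the laminin chain of the Schwann cell basal lamina, went from 690.3 ± 33.3 to 452.0 ± 23.4 CPM, Col4a5 from 38.1 ± 3.51 to 15.4 ± 1.19 CPM and its neighbour Col4a6 from 1.93 ± 0.658 to 0.198 ± 0.162 CPM. Nid2 fell 1.29-fold. Lama1 rose from 3.17 ± 0.726 to 6.22 ± 0.311 CPM, a call that was lost without cKO 1, cKO 2, cKO 3 or WT 2. The list was not called (camera adjusted p = 0.101, and adjusted p = 0.689 with an estimated correlation), but it was called lower with a filter of 50 counts in 3 libraries, without cKO 2 and with the muscle level as a covariate (camera adjusted p = 0.0377, 0.0402 and 0.0018; adjusted p = 0.706, 0.699 and 0.654 with an estimated correlation).

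Known targets of YAP, TAZ and TEAD did not move as a group in these counts of whole nerve. Of 25 tested, 4 fell and 1 rose (4 and 2 adjusted over the list alone), with a median log2 fold change of 0.07 and a camera adjusted p of 0.644 (adjusted p = 0.762 with an estimated correlation). With the muscle level as a covariate the list's direction turned to lower, without a call (camera adjusted p = 0.606, and adjusted p = 0.833 with an estimated correlation). The widely used targets Ctgf (log2 0.47 ± 0.23), Cyr61 (0.16 ± 0.09) and Ankrd1 (0.77 ± 0.57) did not pass. Ankrd1 was low, at 0.455 ± 0.245 CPM in WT and 0.788 ± 0.375 CPM in the cKO-labelled libraries. Igfbp3 rose 1.49-fold, while Lats2, Ajuba, Arhgef17 and Amotl2 were 1.27-fold to 1.46-fold lower. With total counts 0 targets were lower and 2 higher by edgeR. Without cKO 1, cKO 3 or WT 2 the count of lower targets was 0, and without cKO 2 it was 1; Igfbp3 lost its call without cKO 3, and without WT 3 3 targets were higher. Of 23 other components of the Hippo pathway, 4 fell and 0 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.208, and adjusted p = 0.72 with an estimated correlation; with the muscle level as a covariate camera adjusted p = 0.0392, and adjusted p = 0.83 with an estimated correlation). The TEAD cofactor Vgll3 fell 2.54-fold from 157.3 ± 28.8 to 61.9 ± 7.52 CPM, Tead4 3.10-fold from 5.42 ± 0.951 to 1.76 ± 0.608 CPM, Tead3 1.45-fold and Fat1 1.30-fold. Vgll3 and Tead4 were called in all 6 fits that left out 1 library, and Tead3 and Fat1 in 2, those without cKO 2 or WT 3. Among 28 focal adhesion and cytoskeletal genes, 4 rose (Parvb, Vcl, Pak1 and Fyn) and 1 fell (Tns3); 4 and 2 were called adjusted over the list alone. Parvb rose 1.70-fold. The higher calls went to 1 without cKO 3 or WT 1 and to 2 without cKO 2 or WT 2, and Tns3 lost its call without cKO 1, cKO 2, cKO 3 or WT 2. That list's median and its test were negative and its mean positive, and it was not called (camera adjusted p = 0.765, and adjusted p = 0.874 with an estimated correlation).

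Among regulators of Schwann cell myelination, Egr2, the transcription factor that drives myelin genes, fell 1.44-fold from 230.8 ± 17.6 to 160.4 ± 3.42 CPM (log2 -0.53 ± 0.09, edgeR adjusted p = 0.00627). Nab1, a partner of Egr2, fell 1.72-fold, and Qk, an RNA-binding protein that acts on myelin transcripts, fell 1.51-fold. Adam22 and Zeb2 also fell, and Lgi4 rose 1.40-fold. That made 5 lower and 1 higher of 17 tested (5 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.205, and adjusted p = 0.689 with an estimated correlation). Without cKO 3, 3 were lower and 0 higher, with Qk and Lgi4 among the calls lost, and without WT 2 3 were lower. Sox10, the lineage's transcription factor, had a log2 fold change of -0.17 ± 0.14 and did not pass. Of 19 genes of immature and repair Schwann cells, 3 rose and 2 fell (the same counts adjusted over the list alone). Tnc, a matrix protein, rose 1.94-fold, Id4 1.87-fold and Sox2 1.68-fold, while Cdh2 fell 1.91-fold and Ngfr, the low-affinity neurotrophin receptor, 1.58-fold. This list was not called (camera adjusted p = 0.0807, and adjusted p = 0.626 with an estimated correlation), but it was called higher with genes of several lists left out and with the filter of 50 counts (camera adjusted p = 0.00607 and 0.0332; adjusted p = 0.428 and 0.618 with an estimated correlation) and by rank-based camera (adjusted p = 0.0402), and Ngfr lost its call without cKO 3 or WT 2. Of 12 markers of nonmyelinating Schwann cells, Scn7a, Cdh2 and Ngfr were lower and 0 higher (4 lower adjusted over the list alone; camera adjusted p = 0.102, and adjusted p = 0.626 with an estimated correlation; called by fry, adjusted p = 0.00958). Scn7a, a sodium channel, fell 7.07-fold from 107.3 ± 25.9 to 15.2 ± 1.56 CPM. Among 15 axon-glia adhesion genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone). Nrcam, a cell adhesion molecule of the node of Ranvier, fell 2.64-fold, Cntn1 2.67-fold and Mpdz 1.74-fold, and Cadm2 rose 1.96-fold. Without cKO 3, 3 were lower and 1 higher, and without cKO 1, WT 1 or WT 2 1 was higher. The median of this list was slightly above 0, its mean and test were negative, and it was not called (camera adjusted p = 0.181, and adjusted p = 0.689 with an estimated correlation).

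No transcript of the lists for dividing cells was called changed when all 6 libraries were used. Of 28 S-phase genes and 30 G2/M-phase genes, 0 were called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted edgeR p under 0.05. The list medians were 0.08 and 0.04 (camera adjusted p = 0.208 and 0.376; adjusted p = 0.846 and 0.874 with an estimated correlation). Mki67, the proliferation marker, stood at 204.9 ± 53.1 CPM in WT and 223.9 ± 7.97 CPM in the cKO-labelled libraries. E2f1 (log2 0.26 ± 0.14), Ccne1 (0.43 ± 0.24), Kif23 (0.38 ± 0.19) and Anln (-0.24 ± 0.18) had the smallest p-values of their lists and did not pass. The library WT 3 lay apart, with 58 of the 58 cell cycle genes below the mean of WT 1 and WT 2 by a median log2 difference of -0.77. Without WT 3, the direction turned: 29 of 30 G2/M-phase genes were negative and 5 were called lower (median -0.24, camera adjusted p = 2.22e-05, and adjusted p = 0.417 with an estimated correlation), and 24 of 28 S-phase genes were negative with 0 called (median -0.12, camera adjusted p = 0.0488, and adjusted p = 0.651 with an estimated correlation). Without WT 1 or WT 2 the G2/M-phase list was instead called higher (camera adjusted p = 0.0384 and 0.0419; adjusted p = 0.767 and 0.836 with an estimated correlation), as was the S-phase list without WT 2 (camera adjusted p = 0.0116, and adjusted p = 0.789 with an estimated correlation), with 0 genes called by edgeR. With the muscle level as a covariate both lists were called higher (camera adjusted p = 9.14e-06 and 0.00056; adjusted p = 0.83 and 0.833 with an estimated correlation). Regulators of entry into the cycle did change. All D-type cyclins rose: Ccnd2 2.53-fold from 97.9 ± 19.5 to 247.4 ± 12.4 CPM, Ccnd3 1.94-fold and Ccnd1 1.60-fold. Of the inhibitors, Cdkn1c rose 1.98-fold from 646.0 ± 98.1 to 1280 ± 199 CPM and Cdkn2a also rose, while Cdkn1b, Cdkn1a and Rb1 were 1.36-fold to 1.47-fold lower. That made 5 higher and 3 lower of 15 in this list (6 and 3 adjusted over the list alone), which was not called as a whole (camera adjusted p = 0.181, and adjusted p = 0.689 with an estimated correlation). The higher calls went to 3 without cKO 2, cKO 3 or WT 1 and the lower ones to 1 without cKO 3.

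Among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, the 12 with the largest falls were Mme, Vat1l, Sema5a, Scn7a, Slit2, Fam178b, Drp2, Dusp14, Frmd3, Adcy1, Zswim5 and Pmp2. Mme, the membrane protease neprilysin, went from 460.1 ± 156 to 44.1 ± 19.7 CPM, a 10.4-fold fall (log2 -3.38 ± 0.37, edgeR adjusted p = 0.000951). The guidance ligands Sema5a and Slit2 fell 8.10-fold and 6.84-fold, Slit2 from 43.8 ± 4.38 to 6.41 ± 0.841 CPM. Vat1l fell 8.37-fold from 330.6 ± 68.3 to 39.6 ± 13.7 CPM, and Adcy1, an adenylyl cyclase, fell 5.27-fold. At the other end, Klk10 (chromosome 7, 43781035 to 43785410), a secreted serine protease, rose 19.9-fold from 1.44 ± 0.572 to 28.9 ± 4.12 CPM (log2 4.32 ± 0.26, edgeR adjusted p = 0.000162). Myh4, Myog, Mybpc2, Actc1, Sln, Mypn, Actn2 and Atp2a1, genes of the contractile apparatus, calcium handling or development of striated muscle, rose 6.26-fold to 9.01-fold. The 12 largest rises among such genes also held 2 near-identical copies of an interferon-induced gene whose reads cannot be assigned with certainty. All 24 kept their call in each fit that left out 1 library, except Myh4 and both copies.

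Skeletal muscle transcripts were higher in each cKO-labelled library than in any WT library. The 19 genes of the muscle list took 0.5597%, 1.153% and 0.7474% of gene counts in cKO 1, 2 and 3 and 0.1997%, 0.05254% and 0.1749% in WT 1, 2 and 3 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of these genes 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 2.35. Acta1, the actin of skeletal muscle, went from 340.7 ± 190.8 to 1828 ± 783 CPM and Ttn, which encodes titin, from 24.2 ± 13.4 to 139.9 ± 27.1 CPM. Camera gave an adjusted p of 7.68e-11 with the preset correlation and an adjusted p of 0.646 with an estimated correlation. Rank-based camera called the list (adjusted p = 1.6e-09) and fry did not (adjusted p = 0.0691). The difference in muscle transcripts between the groups therefore runs alongside that of the myelin, cholesterol and other gene groups.

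Lymphocyte and granulocyte markers were also higher, 4 of 13 called and 0 lower (5 adjusted over the list alone; median log2 1.01; camera adjusted p = 8.68e-06, and adjusted p = 0.492 with an estimated correlation). Cd79a, a subunit of the B-cell receptor, rose 6.11-fold from 0.608 ± 0.167 to 3.73 ± 1.30 CPM. Cd79b and Cd3g were also called. Mast cell markers had 2 of 9 higher, Tpsb2 (2.18-fold) and Mcpt4 (1.96-fold), and 6 adjusted over the list alone (camera adjusted p = 0.00686, and adjusted p = 0.689 with an estimated correlation). The count was 0 without cKO 3 or WT 1, 1 without cKO 1 or WT 2 and 4 without cKO 2.

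In the macrophage list, 1 of 19 genes was called higher, Ptprc, which other leukocytes also express. Adjusted over the list alone 0 were called (camera adjusted p = 0.0397). Among adipocyte markers Cidea was the 1 of 13 called higher, with 1 adjusted over the list alone (camera adjusted p = 0.0122). Of 19 fibroblast markers 3 were higher, Pi16, Etv1 and Clec3b (4 adjusted over the list alone; camera adjusted p = 0.095). Of 14 pericyte and smooth muscle markers 1 was higher, Cspg4 (2 adjusted over the list alone; camera adjusted p = 0.121). Of 16 endothelial markers 0 were called (0 adjusted over the list alone; 3 with an unadjusted edgeR p under 0.05, 1 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.0511). Adjusted p-values with an estimated correlation were between 0.689 and 0.707 for these lists. With the muscle level as a covariate the macrophage and adipocyte lists were not called (camera adjusted p = 0.549 and 0.941), nor was the macrophage list without cKO 1, cKO 3, WT 1 or WT 2. The endothelial list was called higher with genes of several lists left out, the filter of 50 counts, the replicate block, rank-based camera and without cKO 1 or WT 3 (camera adjusted p from 4.06e-06 to 0.0465), and the fibroblast and pericyte lists without WT 3 (camera adjusted p = 0.000286 and 9.64e-05). Rank-based camera aside, camera with an estimated correlation made none of these calls (adjusted p from 0.417 to 0.811). Single libraries changed these counts: without WT 3, 12 adipocyte, 10 endothelial, 9 pericyte and smooth muscle, 7 fibroblast and 6 macrophage markers were called higher. The fibroblast calls were lost without any one of the other libraries, the call of Ptprc without any one library but cKO 1, the pericyte call without cKO 3 and the adipocyte call without cKO 2. Of 13 perineurial markers Stra6 was higher and Sfrp5 and Itgb4 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.819), and Stra6 kept its call only without WT 3. The lower calls of that list went to 0 without cKO 3 and to 1 without cKO 1, WT 2 or WT 3. Of 8 melanocyte and neural crest genes Tfap2a was higher, at 1.56 ± 0.375 CPM against 0.270 ± 0.0170 CPM (2 adjusted over the list alone; camera adjusted p = 0.241). Of 12 neuronal genes 0 were called, with 5 at an unadjusted edgeR p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.0602; called higher with the filter of 50 counts, the replicate block, rank-based camera and without cKO 2 or WT 3, camera adjusted p from 0.00503 to 0.0402). Ranks aside, camera with an estimated correlation did not call the neuronal list in those settings (adjusted p from 0.611 to 0.706). Of 6 red blood cell genes 0 were called, with 1 at an unadjusted edgeR p under 0.05, 1 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.102). Without WT 1, 3 red blood cell genes were called higher, as was the list (camera adjusted p = 0.00122), which the replicate block called too (camera adjusted p = 0.0216). Camera with an estimated correlation made neither call (adjusted p = 0.603 and 0.685).

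Among lists of RNA quality, 3 of 15 immediate early genes rose (Btg2, Dusp1 and Junb) and 1 fell (Atf3, from 21.0 ± 1.62 to 10.6 ± 1.85 CPM), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.115, and 0.0384 without WT 1). None of the higher calls was made without cKO 2, cKO 3 or WT 2, and Atf3 was called in all 6 fits that left out 1 library. Of 16 heat shock and unfolded protein response genes Hspb1 was higher (2.14-fold; 1 adjusted over the list alone; camera adjusted p = 0.413), a call made only without WT 2 or WT 3 among the fits that left out 1 library. Of 25 cytosolic ribosomal protein genes 0 were called by edgeR or limma-voom and 1 by DESeq2, with 7 at an unadjusted edgeR p under 0.05, and the median log2 fold change was 0.22 (camera adjusted p = 0.00321, and 0.2 and 0.0526 without cKO 1 and WT 1). Of 5 sex chromosome marker genes 0 were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.285). With an estimated correlation, the adjusted p was 0.689 for all of these lists but the heat shock list, where it was 0.797. In all, camera with the preset correlation called 9 of the 32 lists, 6 higher and 3 lower, and 0 with an estimated correlation, with all 6 libraries, with the filter of 50 counts, the replicate block, genes of several lists left out or the muscle level as a covariate, and in each fit that left out 1 library (lowest adjusted p = 0.417 with an estimated correlation). The other 9 splits of the 6 libraries gave 7 to 17 called lists, so 9 called lists are not particular to the real split. Those splits gave 0 genes called by edgeR, with 88 to 1248 genes at an unadjusted p under 0.05. Each of them has libraries of both groups on either side, so part of the difference between the groups stays in its contrast. The rest of that difference adds to the spread, so neither count tests chance.

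**Figure D3:**
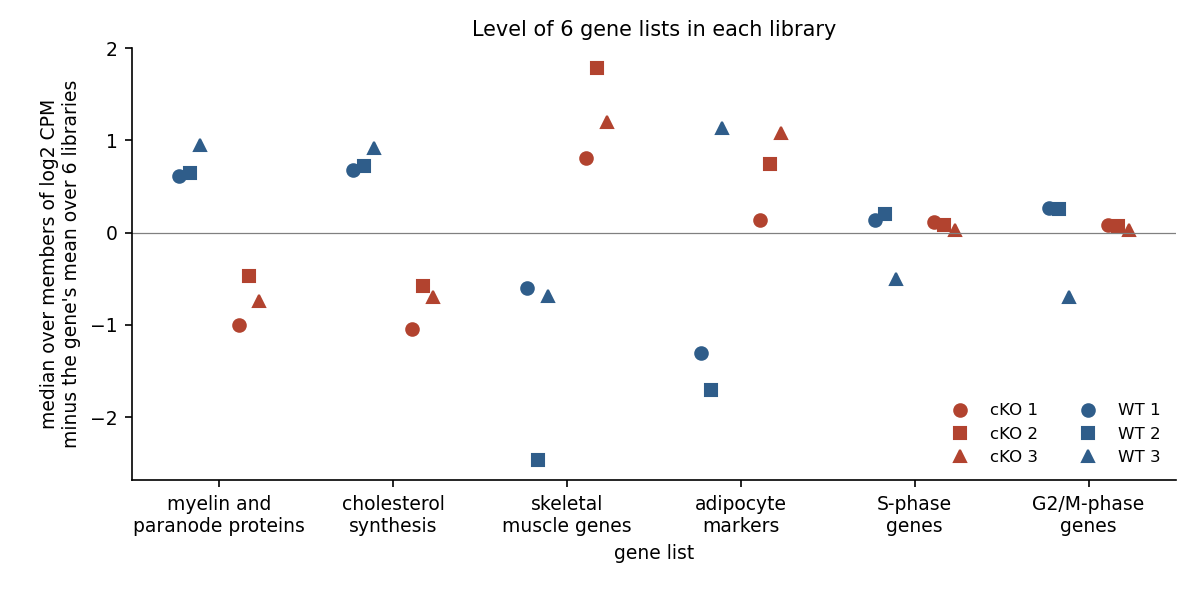
Level of 6 gene lists in each library, as the median over members of log2 CPM minus the gene's mean over the 6 libraries (symbols give the replicate, blue WT and red cKO-labelled). Myelin, cholesterol and muscle genes separate the groups, WT 3 has the lowest S-phase and G2/M-phase levels (-0.50 and -0.70), and the adipocyte markers of WT 3 (1.13) lie at the level of cKO 3 (1.08).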

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

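The tests of a single tissue source for the muscle genes, of genes still higher at a given muscle level, of muscle attached by genotype, of a lower share of Schwann cell RNA and of adipose dilution of WT 3 were chosen only after the result was seen.

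Reads that the counting program gave to no gene, which no comparison of the report uses, stood above the WT level in each cKO-labelled library. They made up 13.97%, 13.24% and 14.26% of all counts in cKO 1, 2 and 3 and 12.07%, 12.17% and 12.64% in WT 1, 2 and 3 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

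Skeletal muscle genes were higher in every cKO-labelled library. The mean of the other muscle genes accounted for a median of 98.5% of a muscle gene's variance over the 6 libraries. For the lowest gene it was 78.6%. A single source of all of them, such as muscle tissue carried along with the nerves, would give high values. The difference between the groups is part of that variance, so genes raised together by genotype could give them too. Among 689 other genes higher in the cKO-labelled libraries, the median correlation of their deviations within groups with the muscle level was 0.54 (quartiles -0.0906 to 0.865). That median lay between the limits set beforehand for and against muscle RNA as the source of all of them. Of the 689 genes, 217 (31.5%) correlated above 0.8, against 4.18% of the genes not called. With the muscle level as a covariate 5 of the 689 genes, Col2a1, Fibin, Klk10, Otop1 and S100a4, were still called higher, and no other of the 14789 tested genes was. Among 14789 genes without an effect, 0.921 would be expected to reach such a p in that direction. That number takes its cutoff from the adjusted p threshold of the same fit, which alone keeps it low, so it is no test beyond the calls. It also treats genes as independent, and the muscle level correlated with the group at 0.883. In that fit these 5 genes stayed higher at a given muscle level, while the part of that level in the others stays open. Whether dissection or genotype set the muscle level cannot be told apart, because every cKO-labelled library has more of it, the lowest lying 1.31 log2 units above the highest WT library while the WT libraries alone spanned 1.94.

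Myelin and cholesterol synthesis genes were lower in the cKO-labelled libraries, with a median log2 fold change of -1.60 over the 46 called members of both lists. A lower share of Schwann cell RNA, from fewer cells or dilution by other tissue, would lower other Schwann lineage genes by a similar amount. But the 7 such genes examined outside the myelin list had a median log2 fold change of -0.163. They ranged from -1.63 ± 0.24 (SE) for Gfra3, the exception and the 1 called, to 0.273 ± 0.191 for S100b. These genes were picked after the result was seen, so they are no independent test. With all libraries thinned to the total of the shallowest, 100% of the 46 were still called, and with the trends of GC content and transcript length removed also 100%, which argues against depth and against those trends as the whole cause. With the muscle level as a covariate 11 were still called, their median going from -1.60 to -1.81 while the median SE grew from 0.153 to 0.315, since that level differs between the groups. A lower expression of these genes in Schwann cells of the cKO-labelled mice is a hypothesis these values leave open.

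Cell cycle genes were lower in WT 3 than in the mean of WT 1 and WT 2, by a median of -0.773 on the log2 scale, in 58 of 58 genes. Adipocyte markers were higher there by a median of 3.12, but dilution of nerve RNA by adipose tissue would lower the myelin genes too, and their median difference was 0.327 (quartiles 0.11 to 0.517; 20 of 24 higher). A more advanced postnatal stage might lower the imprinted genes as well, and their median difference was 0.0281 with 9 lower and 11 higher, which decides nothing. The ages are not given in the sources used here.

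The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1618 changed genes, 706 higher and 912 lower, and 1 of the 10 splits, the real one, gave as many of each; the highest of the others was 0 by edgeR, with up to 1248 genes at an unadjusted p under 0.05. For gene lists, 9 of the 10 splits gave at least the 9 lists of the real split, and the highest other gave 17. Every other split mixes both groups on each side, so a difference between the groups stays partly in its contrast and widens its spread. The counts of genes and lists in those splits are therefore no test of chance.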

How the results depend on the processing

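The tests with thinned counts, with the muscle level as a covariate and with the GC and length trends removed were chosen only after the result was seen; the other settings were fixed before. Total counts gave 1273 higher and 606 lower genes. The replicate block gave 1104 changed genes (461 higher, 643 lower), 12 lists and a Wwtr1 log2 fold change of 0.40 (edgeR adjusted p = 0.0713); the numbers do not pair the samples, as deviations of same-numbered samples correlated between -0.207 and 0.0724 and 2 of 6 samples were closest to their own number. The muscle covariate gave 38 changed genes (5 higher, 33 lower) and Wwtr1 at 0.56 (edgeR adjusted p = 0.448), and turned Atp2a1 (-0.23), Mybpc2 (-0.39) and Myh4 (-1.20) negative; the covariate differs between the groups, which widens the errors. It added camera calls of 6 lists (laminin receptors, dystroglycan partners, laminins and Hippo components lower, S-phase and G2/M-phase genes higher). The calls of the macrophage and adipocyte lists ended. That of the muscle list ended too, which was fixed beforehand, because the covariate is the mean of that list's own genes, Myh4 among them. An estimated correlation called 0 lists. Fry called 5: the lists of myelin, cholesterol synthesis, fatty acid synthesis, nonmyelinating Schwann cells, and lymphocytes and granulocytes. Where no reason is given, the cause was not tested. Of other settings, DESeq2 gave 2254 changed genes, limma-voom 1643, the GC and length correction 1746 and thinned counts 1583.

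Fits that left out 1 library, with fewer samples, gave 735 to 2195 changed genes, 276 to 1075 higher, 459 to 1120 lower, 8 to 15 called lists, Yap1 from -0.24 to -0.18 and Wwtr1 from 0.33 to 0.44. Camera adjusted p-values ran from 0.0116 to 0.552 for S-phase and from 2.22e-05 to 0.619 for G2/M-phase genes. Both lists were lower only without WT 3 (0.0488 and 2.22e-05). Of the 120 named genes 90 were called, 60 of them in all 6 such fits and 15 with the muscle covariate. Depth limits the lowest genes, since 0 counts allow up to 0.122 CPM in the shallowest library.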

Other observations

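All tests in this part were chosen only after the result was seen, on lists made from genes noticed among the changed ones, so their p-values are not independent evidence.

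Genes of sphingolipid metabolism, the pathway to the galactolipids of myelin and their breakdown, had 6 of 19 members lower in the cKO-labelled libraries and 0 higher (camera adjusted p = 4.45e-05, and adjusted p = 0.0732 with an estimated correlation). Sptlc2, a subunit of the first enzyme, had a log2 fold change of -0.98 ± 0.10 (SE), and Cers4, Gal3st1 and Cers2 were also lower, as were Galc and Asah1, enzymes of breakdown. Among 24 axon guidance ligands 4 were lower and 0 higher, Slit2, Sema5a, Sema6d (-1.82 ± 0.13) and Sema7a (-0.78 ± 0.15). That list's median was slightly above 0 while its test was negative (camera adjusted p = 0.75, and adjusted p = 0.862 with an estimated correlation). Of 18 glycolysis genes 7 were higher, among them Slc16a3 (1.04 ± 0.14), Gapdh (0.61 ± 0.09) and Ldha (0.50 ± 0.09) and also Pfkm (0.69 ± 0.16) and Aldoa (0.58 ± 0.11), which skeletal muscle expresses highly, and Aldoc was lower (-2.79 ± 0.42; camera adjusted p = 0.000927, and adjusted p = 0.204 with an estimated correlation). Skeletal muscle genes were higher in the same libraries, and the median level of both lists, as log2 CPM minus each gene's mean over the 6 libraries, was highest in cKO 2 (0.219 for glycolysis and 1.79 for muscle, against 0.0718 and 0.81 in cKO 1 and 0.0834 and 1.20 in cKO 3). In WT 1, 2 and 3 the levels were -0.119, -0.163 and -0.167 for glycolysis and -0.604, -2.47 and -0.684 for muscle. WT 2, by far the lowest for muscle, lay close to WT 3 for glycolysis. Whether muscle gave part of the glycolysis rise was not tested.

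Imprinted genes, a network active in growing tissue, had 8 of 20 members higher and 0 lower (camera adjusted p = 0.000646, and adjusted p = 0.0732 with an estimated correlation). Among them Rian had a log2 fold change of 0.59 ± 0.09, Zdbf2 of 1.02 ± 0.15, Meg3 of 0.90 ± 0.20 and H19 of 0.52 ± 0.12, beside Cdkn1c. H19 and Mirg, another called member, ranked over the 6 libraries as the skeletal muscle level did, while Zdbf2 and Cdkn1c were highest in cKO 1. The median level of the list was 0.107 in cKO 2, which held the most muscle, against 0.181 in cKO 1 and 0.189 in cKO 3. Whether muscle gave part of the rise was not tested. Genes induced by interferon-gamma had 12 of 26 higher and 0 lower (camera adjusted p = 2.66e-09, and adjusted p = 0.204 with an estimated correlation), among them Serpina3g (2.37 ± 0.31) and Cxcl9 (2.48 ± 0.46). The level of that list, as the median of log2 CPM minus each gene's mean over the 6 libraries, was 0.00736, 0.721 and 1.04 in cKO 1, 2 and 3 and -0.677, -0.936 and -0.0335 in WT 1, 2 and 3, so cKO 1 lay close to WT 3. Genes typical of lymphoid organs had 9 of 14 higher and 0 lower (camera adjusted p = 4.1e-10, and adjusted p = 0.0732 with an estimated correlation), 3 of them also in the list of lymphocyte markers. Lymph node tissue carried along with the nerves is a candidate source that may give such genes, but levels were low, with Ccl19 at 4.77 CPM and Cxcl13 at 1.51 CPM in the cKO-labelled libraries, and no test here separates it from immune cells within the nerve.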
